A study of Chlorocebus aethiops with 10 samples.

How the data were processed

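Liver biopsies of 10 female African green monkeys were profiled on one-colour arrays, 1 array per animal, in 2 groups of 5. Per the labels' protocols, double-stranded cDNA was made from 1 µg of total RNA and labelled with Cy3. The antimiR compounds were given under the skin at 20 mg/kg on day 0 and at 5 mg/kg each week after that, and vehicle animals received 0.9% saline. The biopsies were taken on day 57, after 8 weeks of treatment. The labels describe 20 animals in 4 groups of 5, allotted at random; the animals given antimiR-33a or antimiR-33b alone were not analysed here. Each array stands for another animal, so the replicates are biological. The labels give no numbers that pair animals across groups and no slide, scan or extraction batch.

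The deposited values are on a log2 scale as used here, centred per array feature by the authors; the scanner, the normalization, the way probes were combined into features, the centring and the log base are not given in the sources used here. The values ran from -2.26 to 2.94 over 45033 features. The median of a feature over the 10 arrays lay within 1e-06 of 0 for 7.30% of features only, and 21.3% of features held a mirrored pair of values nearest 0, which centring on the median of a larger, even number of arrays would leave. The values of 46.2% of features were whole multiples of 2^-20, and those of 93.9% were whole multiples of 2^-21, within 0.1 of a step. Such steps are those of single-precision numbers between 8 and 16 and between 4 and 8, respectively. Log10 intensities could reach the second range but not the first, so only the 46.2% argue against log10. A natural log scale is not excluded, and under it every fold given here would lie further from 1. Centring removed the level of each feature, so a value is comparable between animals and not between genes, and signal over background is unknown.

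A probe table gave 1 gene symbol for 18188 features, several symbols for 0 and none for 26845. The symbols are those of human genes in an older annotation, and 2 symbols of the gene lists were matched through their gene numbers. The probe sequences were not used here, so mismatches between probes and monkey transcripts were not examined. Planned rules that needed levels could not be applied to centred values: the feature with the highest mean standing for a gene, and a filter on the dimmest features. The mean over a gene's features took the place of the first, which gave 16583 genes, 1286 of them with more than 1 feature. The array medians ran from -0.054 to 0.061, a range of 0.12, under the limit of 0.2 set before the data were examined, so the values were used as deposited. Of the 191 called genes with several features, 188 had features that all moved the same way, against 841 of all 1286 genes with several features. Calls were made on the mean of the same features, which favours genes whose features agree, so this is no separate support for the calls.

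Gene differences, antimiR-33a/b minus vehicle, were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 10 arrays, no covariate), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. ABCA1, the best established miR-33 target, was also tested by an exact two-sided permutation test over the 252 assignments of 10 animals, whose smallest p is 0.0079. The 24 gene lists were written before the data were examined; 309 of their 334 genes were measured. The 23 lists with at least 3 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which asks whether the members move on balance one way, were run beside it. Some genes stand in more than 1 list.

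The rule for named genes was fixed at the same time. It takes every measured gene of the list of reported miR-33 targets in lipid and energy metabolism and of the miR-33 host genes. Next come the 10 largest rises and the 10 largest falls among called genes whose treated values all lay on one side of the vehicle values. From every other list it takes up to 4 members with the smallest p. Genes outside the rule are marked as chosen after their values were seen. A further 19 gene families were defined by symbol patterns after the values had been examined. They hold 9 housekeeping families with 532 genes, 5 families that liver does not normally express (olfactory, taste and vomeronasal receptors, keratin-associated proteins, cornified envelope proteins and beta-defensins) with 513 genes, and 5 others. For each animal the median of the first set minus that of the second gave a contrast of expressed against silent families.

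Fixed in advance were fits after quantile normalization, a shift of every array to the same median, every feature tested on its own, eBayes with trend and robust settings, array weights, an exact permutation test per gene and fits without each animal in turn. Added after the data were examined were the feature with the largest spread as the gene's value, a fit on features whose steps show values of 8 or more before centring, a fit with the family contrast as a covariate, and camera with an estimated correlation under that covariate. A comparison of genes with and without miR-33 seed sites in their 3' untranslated regions was planned and not run, since no transcript sequences were used here. Array number limits the precision. The fit was tested on simulated data with the real means and spreads of the 16583 genes, of which 200 were changed. It recovered 98.5% of those changed by 1.00, 79.1% of those changed by 0.50 and 16.4% of those changed by 0.25 on the log2 scale, with 10 false calls among 139. The simulated genes varied independently of each other, unlike the real ones, and far fewer were changed than were called in the real fit. The shares recovered and falsely called therefore need not hold for the real fit. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.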

Results

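Expression was measured in liver biopsies of obese adult female African green monkeys (Chlorocebus aethiops) kept on a high-fat diet for 12 weeks. Treated animals (n = 5) had received antimiR-33a/b, a locked nucleic acid oligonucleotide directed at the microRNAs miR-33a and miR-33b, and control animals (n = 5) had received saline vehicle. MiR-33a and miR-33b are encoded in introns of SREBF2 and SREBF1, the genes of the sterol-regulating transcription factors SREBP2 and SREBP1. Each array reported 45033 features, of which 18188 carried a gene symbol and gave 16583 genes. Values were centred per feature, so only differences between animals are given, taken as log2 units although the log base was not stated. Array medians ranged from -0.054 to 0.061, and no pair of arrays held identical values. Signal over background is unknown, and the precision is set by the number of arrays.

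The comparison of treated with vehicle animals asked how the liver transcriptome differed after 8 weeks of miR-33 inhibition. Among reported miR-33 targets, ABCA1, the cholesterol efflux transporter, rose 1.37-fold in treated livers. CROT, a peroxisomal carnitine acyltransferase, rose 1.60-fold, and NRIP1, a nuclear receptor corepressor, rose 1.31-fold. The miR-33a host gene SREBF2 fell to 0.873-fold. Beyond these, ELOVL5, GPAM and ACLY, 3 of 17 measured fatty acid and triglyceride synthesis genes, and the bile acid uptake transporters SLCO1B1 and SLCO1B3 rose. The drug-metabolizing enzyme CYP1A2 fell. As wholes, the fatty acid synthesis and bile acid lists did not pass in camera (adjusted p = 0.488 and 0.669). In limma, 3399 of 16583 genes (20.5%) passed an adjusted p of 0.05, 2271 of them higher and 1128 lower in treated animals. Counts of called list members given below are to be read against this share. None of the genes in this paragraph stayed called when a contrast of expressed against silent gene families, described below, was added to the fit as a covariate. Their differences on the log2 scale then ranged from -0.29 for CYP1A2 (-0.47 without the covariate) to 0.59 for GPAM (0.69). ABCA1 was unchanged at 0.45, with a larger SE. NRIP1 (0.36 against 0.39) and ACLY (0.36 against 0.42) changed little. ELOVL5 (0.52 against 0.86) and SREBF2 (-0.11 against -0.20) shrank more, and CROT went from 0.67 to 0.063.

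ABCA1 had a mean of -0.26 ± 0.23 (SD, n = 5) in vehicle animals and 0.19 ± 0.17 (SD, n = 5) in treated animals. The difference was 0.45 on the log2 scale (SE 0.11, 95% confidence interval 0.21 to 0.69), with p = 0.0159 in an exact two-sided permutation test and a limma adjusted p of 0.0141. Values were 0.45, 0.23, 0.14, 0.13 and -0.018 in treated animals, and 4 of these lay above the highest vehicle value of 0.018.

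Of the 20 measured genes reported as miR-33 targets in lipid, bile acid and energy metabolism, 4 rose, 0 fell and 16 did not pass the test over all genes, while 6 passed when adjusted over the list alone. With 4 of 20, the list was called at about the share of all genes, 20.5%. The 4 were ABCA1, CROT (difference 0.67, SE 0.17, limma adjusted p = 0.0171), NRIP1 (0.39, SE 0.085, adjusted p = 0.0096) and PRKAA1, a catalytic subunit of the energy sensor AMPK (0.46, SE 0.15, adjusted p = 0.0433). NRIP1 was higher in all 5 treated animals than in any vehicle animal. The sterol transporter ABCG1 (0.40, adjusted p = 0.0535) and CYP7A1, the rate-limiting enzyme of bile acid synthesis (0.59, adjusted p = 0.0632), passed over the list alone and not over all genes. Differences were 0.38 for PDK4, 0.34 for HADHB, 0.31 for PPARGC1A, 0.14 for G6PC1, 0.13 for SLC25A25, 0.12 for PCK1, 0.11 for NCOA1, 0.10 for NFYC and 0.10 for NPC1. They were 0.057 for ABCB11, 0.042 for SIRT6, -0.085 for IRS2, -0.10 for ATP8B1 and -0.18 for CPT1A, none past the threshold. The difference was positive for 17 of the 20, with a median of 0.13, and the list missed the camera threshold (p = 0.0214, adjusted p = 0.123; p = 0.24 with an estimated correlation). Without vehicle animal 4 the list's median was 0.32 and its adjusted camera p was 0.0164. With the family contrast as a covariate the median was 0.045 and the adjusted camera p was 0.369 (0.711 with an estimated correlation).

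The host gene SREBF2 fell by 0.20 (SE 0.061, limma adjusted p = 0.0380), with all treated values below all vehicle values, and SREBF1 differed by -0.10 (adjusted p = 0.418). PRKAA1 missed the threshold without any 1 of 6 animals (adjusted p up to 0.0981) and SREBF2 without any 1 of 7 (up to 0.0950), while ABCA1, CROT and NRIP1 passed in all 10 fits that left out 1 animal. PRKAA1 also missed it after quantile normalization (adjusted p = 0.0767), after a shift of the arrays to the same median (0.0573) and with trend and robust settings (0.0518). With the contrast of expressed against silent gene families as a covariate, added after the data were examined, ABCA1 differed by 0.45 (SE 0.18, adjusted p = 0.123), NRIP1 by 0.36 (SE 0.14, adjusted p = 0.106), PRKAA1 by 0.48 (SE 0.25, adjusted p = 0.212), CROT by 0.063 (SE 0.17, adjusted p = 0.831) and SREBF2 by -0.11 (SE 0.083, adjusted p = 0.409).

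**Figure D1:**
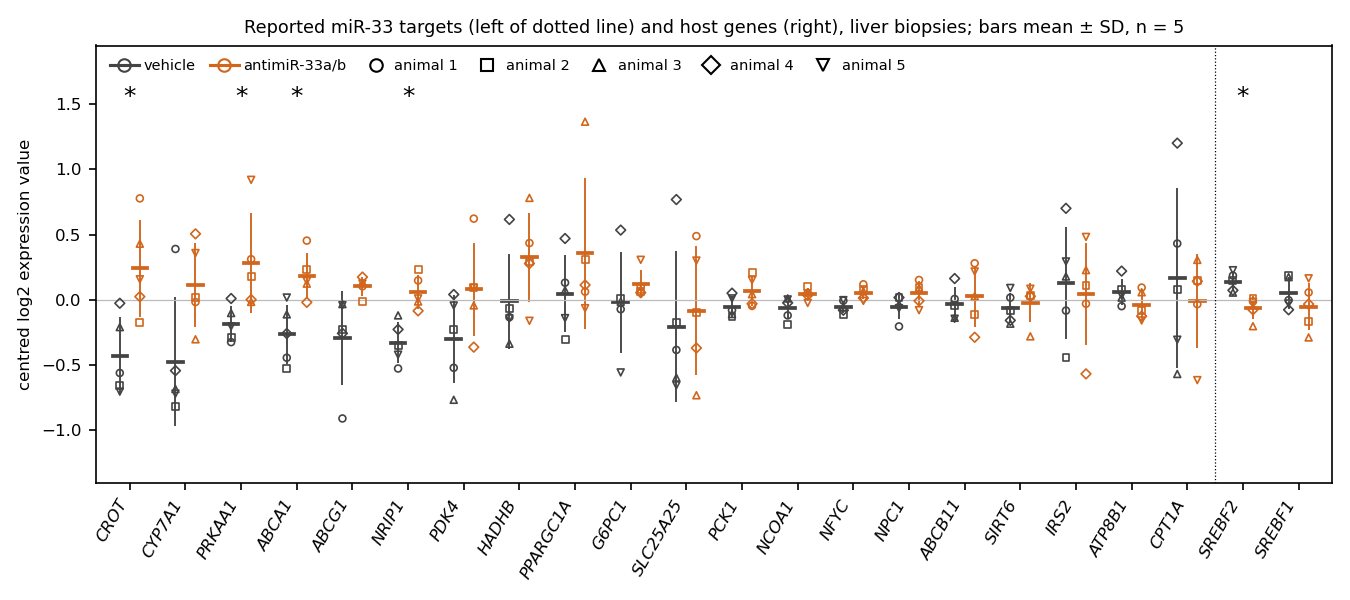
Centred log2 expression values (y axis) of the 20 reported miR-33 targets and, right of the dotted line, the 2 host genes (x axis) in each of 5 vehicle (grey) and 5 antimiR-33a/b (orange) animals; horizontal bars are means, vertical lines SD, marker shapes animals, and asterisks mark a limma adjusted p under 0.05. ABCA1, CROT, NRIP1 and PRKAA1 lie higher in treated animals and SREBF2 lies lower by 0.20, while vehicle animal 4 has the highest vehicle values of CROT, HADHB and CPT1A.

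Among the 11 other reported miR-33 targets (cell cycle, autophagy and other functions), PIM1, a serine/threonine kinase, rose by 0.32 (adjusted p = 0.0228) and TWIST1, a transcription factor, fell by 0.24 (adjusted p = 0.0376), and 9 did not pass; 2 passed when adjusted over the list alone. Without 3 and 7 of the single animals, respectively, PIM1 and TWIST1 missed the threshold (adjusted p up to 0.0586 and 0.0802), and PIM1 also missed it after quantile normalization. Given the family contrast as a covariate, PIM1 differed by 0.087 (adjusted p = 0.610) and TWIST1 by -0.052 (adjusted p = 0.730).

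In fatty acid and triglyceride synthesis, 3 of 17 measured genes rose, 0 fell, and 3 passed when adjusted over the list alone. ELOVL5, a fatty acid elongase, rose by 0.86 (SE 0.17, limma adjusted p = 0.0053). GPAM, which starts glycerolipid synthesis, rose by 0.69 (SE 0.13, adjusted p = 0.0044), and ACLY, which supplies cytosolic acetyl-CoA, rose by 0.42 (SE 0.084, adjusted p = 0.0061). Of 19 genes of cholesterol synthesis, EBP rose by 0.26, SC5D rose by 0.39 and SREBF2 fell, 16 did not pass, and 0 passed in limma when adjusted over the list alone, with 4 at an unadjusted p under 0.05. EBP and SC5D missed the threshold without 7 and 8 of the single animals (adjusted p up to 0.0886 and 0.101). Both also missed it after quantile normalization and after the shift of arrays to the same median, and SC5D with trend and robust settings. With the family contrast as a covariate ELOVL5 differed by 0.52 (adjusted p = 0.18), GPAM by 0.59 (0.0904), ACLY by 0.36 (0.0995), EBP by 0.078 (0.657) and SC5D by 0.037 (0.896). In fatty acid oxidation and ketogenesis, CROT and ACADM (0.47, adjusted p = 0.0482), the medium-chain acyl-CoA dehydrogenase, rose, 23 of 25 genes did not pass, and 1 passed when adjusted over the list alone. The difference was positive for 20 of the 25, with a median of 0.25 and an adjusted camera p of 0.245 (adjusted p = 0.984 with an estimated correlation); without vehicle animal 4 the median was 0.33 and the adjusted camera p was 0.0020. ACADM missed the threshold without 8 of the single animals (adjusted p up to 0.117), after the shift of arrays and with trend and robust settings, and with the family contrast as a covariate it differed by -0.042 and the list's median was -0.16. The list then passed limma's camera at the preset correlation (adjusted p = 4.7e-06) and missed it with an estimated correlation (adjusted p = 0.433).

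Of 19 genes of bile acid synthesis and transport, the hepatic uptake transporters SLCO1B1 (0.47, SE 0.073, limma adjusted p = 0.0021) and SLCO1B3 (0.48, SE 0.082, adjusted p = 0.0032) rose in all 5 treated animals above the vehicle range. SLC51B, a subunit of the basolateral bile acid exporter, fell by 0.32 (adjusted p = 0.0232), 16 did not pass, and 6 passed when adjusted over the list alone. Among 20 apolipoprotein and lipoprotein genes, APOH (0.28, adjusted p = 0.0116) and MTTP (0.38, adjusted p = 0.0260), the transfer protein needed to load lipid onto apolipoprotein B, rose, APOC3 fell by 0.31 (adjusted p = 0.0207), and 3 passed when adjusted over the list alone. Of 11 LXR target genes, ABCA1 and ABCG5 (0.56, adjusted p = 0.0475), a sterol transporter, rose, and 3 passed when adjusted over the list alone. Of 17 genes of glucose handling and insulin signalling, PIK3R1 (0.37, adjusted p = 0.0156) and the glucose transporter SLC2A2 (0.48, adjusted p = 0.0437) rose, and 1 passed when adjusted over the list alone. SLC51B, MTTP, ABCG5, SLC2A2 and APOC3 missed the threshold without 4, 4, 8, 7 and 1 of the single animals, with adjusted p up to 0.0626, 0.0620, 0.108, 0.105 and 0.0517. MTTP, ABCG5 and SLC2A2 also missed it after quantile normalization, ABCG5 and SLC2A2 after the shift of arrays, and MTTP and ABCG5 with trend and robust settings. With the family contrast as a covariate SLCO1B1 differed by 0.39 (adjusted p = 0.0537), SLCO1B3 by 0.39 (0.0749), SLC51B by -0.087 (0.615), MTTP by 0.10 (0.646) and SLC2A2 by 0.095 (0.795). APOH, by 0.31 (0.0733), and PIK3R1, by 0.40 (0.0998), also missed the threshold, APOC3 (-0.45, 0.0486) stayed past it, ABCG5 differed by -0.21 (0.239), and the median of the LXR list was -0.21.

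CYP1A2 was the 1 gene of 11 in drug metabolism that passed, and it fell by 0.47 (SE 0.069, limma adjusted p = 0.0017; 1 passed when adjusted over the list alone), while UGT1A1 differed by 0.22 (adjusted p = 0.0881). In limma, 0 of 16 interferon-stimulated genes and 0 of 15 genes of p53 and endoplasmic reticulum stress passed, over all genes or adjusted over the list alone; 4 and 2 genes had an unadjusted p under 0.05. Among these, IFI44 and IFIT2 differed by 0.33 and HERPUD1 by 0.37. Of 19 acute phase genes, SOCS3, an inhibitor of cytokine signalling, fell by 0.33 (adjusted p = 0.0186) and NFKBIA, an inhibitor of NF-kappaB, rose by 0.40 (adjusted p = 0.0414); 1 passed when adjusted over the list alone. NFKBIA missed the threshold without 8 of the single animals (adjusted p up to 0.0920), after quantile normalization and after the shift of arrays. Given the family contrast as a covariate, CYP1A2 differed by -0.29 (adjusted p = 0.0510), SOCS3 by -0.26 (0.209) and NFKBIA by 0.29 (0.356).

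Cell division genes rose in 7 of 21 cases and fell in 0, and 11 passed when adjusted over the list alone. They included the replication helicase subunits MCM3 (0.37, adjusted p = 0.0154) and MCM4 (0.23, adjusted p = 0.0225), the mitotic cyclin CCNB1 (0.30, adjusted p = 0.0165) and the ribonucleotide reductase subunit RRM2 (0.33, adjusted p = 0.0205). MCM4 and RRM2 each missed the threshold without 2 of the single animals (adjusted p up to 0.0606 and 0.0540), and with the family contrast as a covariate MCM3 differed by 0.14 (0.455), MCM4 by 0.15 (0.257), CCNB1 by 0.30 (0.121) and RRM2 by 0.48 (0.0462). The list missed the threshold in camera (p = 0.0041, adjusted p = 0.0949; p = 0.231 with an estimated correlation) and passed it without vehicle animal 3 (adjusted p = 0.0493), treated animal 1 (0.0253) or treated animal 5 (0.0370).

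Hepatocyte markers rose in 5 of 11 cases and fell in 0, and 7 passed when adjusted over the list alone. ALB rose by 0.44 (SE 0.091, limma adjusted p = 0.0072), TF by 0.31 (adjusted p = 0.0129), AMBP by 0.30 (adjusted p = 0.0104), AHSG by 0.27 (adjusted p = 0.0262) and TTR, named after its value was seen, by 0.26 (adjusted p = 0.0294). AHSG missed the threshold without 5 of the single animals (adjusted p up to 0.0712) and with trend and robust settings. The list's adjusted camera p was 0.097 (p = 0.285 with an estimated correlation), and 0.0164 without vehicle animal 4 and 0.0253 without treated animal 1. It was 0.542 with the family contrast as a covariate. Of the T and NK cell markers, the cytotoxic granule genes NKG7 (-0.31, adjusted p = 0.0182) and GNLY (-0.20, adjusted p = 0.0414) and the chemokine CCL5 (-0.28, adjusted p = 0.0234) fell, CD247 rose by 0.18 (adjusted p = 0.0457), 7 of 11 did not pass, and 5 passed when adjusted over the list alone. GNLY, CCL5 and CD247 missed the threshold without 7, 3 and 9 of the single animals (adjusted p up to 0.0942, 0.0540 and 0.0965), and CD247 also after quantile normalization and with trend and robust settings. Beside the family contrast as a covariate, NKG7 differed by -0.039 (adjusted p = 0.748), GNLY by -0.032 (0.793), CCL5 by -0.26 (0.168) and CD247 by 0.26 (0.0744). Stellate cell and matrix markers TIMP1 (0.36, adjusted p = 0.0067), LRAT (0.33, adjusted p = 0.0179) and RGS5 (0.34, adjusted p = 0.0223) rose among 12, with 3 past when adjusted over the list alone. The endothelial markers TEK (0.37, adjusted p = 0.0207) and STAB2 (0.33, adjusted p = 0.0322) rose among 10, with 2 past when adjusted over the list alone. LRAT, RGS5, TEK and STAB2 missed the threshold without 1, 1, 2 and 4 of the single animals (adjusted p up to 0.0504, 0.0537, 0.0548 and 0.0802), and STAB2 also after quantile normalization. With the family contrast as a covariate ALB and TIMP1 stayed past the threshold, while TF (0.38), AMBP (0.30), AHSG (0.35), LRAT (0.35) and RGS5 (0.39) missed it with differences at least as large as before. TEK (0.28, adjusted p = 0.25) and STAB2 (0.19, adjusted p = 0.405) missed it with smaller ones. All 3 list medians were then lower: 0.11 against 0.26 for hepatocyte, 0.16 against 0.23 for stellate and -0.016 against 0.21 for endothelial markers.

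Plasma cell markers TNFRSF17 (0.23, adjusted p = 0.0416) and MZB1 (0.26, adjusted p = 0.0421) rose among 7 B and plasma cell markers, with 3 past when adjusted over the list alone; without 8 and 7 of the single animals they missed the threshold (adjusted p up to 0.105 and 0.103), and TNFRSF17 also with trend and robust settings. In limma 0 of 8 cholangiocyte, 0 of 11 macrophage and 0 of 7 red cell and neutrophil markers passed, over all genes or adjusted over the list alone, with 1, 1 and 2 genes at an unadjusted p under 0.05. Differences were -0.23 for SOX9, 0.34 for LYZ and 1.25 for HBB (adjusted p = 0.0551), whose vehicle values had an SD of 1.01. Of 10 muscle and fat markers, CKM fell by 0.31 (adjusted p = 0.0063) and the lipid droplet gene PLIN1 rose by 0.60 (adjusted p = 0.0234), and 3 passed when adjusted over the list alone. PLIN1 missed the threshold without 4 of the single animals (adjusted p up to 0.0624) and after quantile normalization, and differed by 0.092 (0.786) with the family contrast as a covariate, with which CKM (-0.18, 0.143), TNFRSF17 (0.24, 0.188) and MZB1 (0.40, 0.0631) also missed it. By camera 0 of the 23 lists passed, 4 had an unadjusted p under 0.05, and 0 did so with an estimated correlation. With the family contrast as a covariate 7 passed at the preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.348). The 7 had medians of -0.37 for macrophage markers (adjusted p = 0.00012), -0.21 for LXR targets, -0.19 for bile acid genes, -0.16 for fatty acid oxidation, -0.13 for cholesterol synthesis, -0.047 for interferon-stimulated and -0.037 for lipoprotein genes. By fry 0 passed for movement in one direction, with 3 at an unadjusted p under 0.05, and 15 passed for change in either direction. Fry does not compare members with other genes. With 20.5% of all genes called, passing for change in either direction is therefore not particular to these lists.

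**Figure D2:**
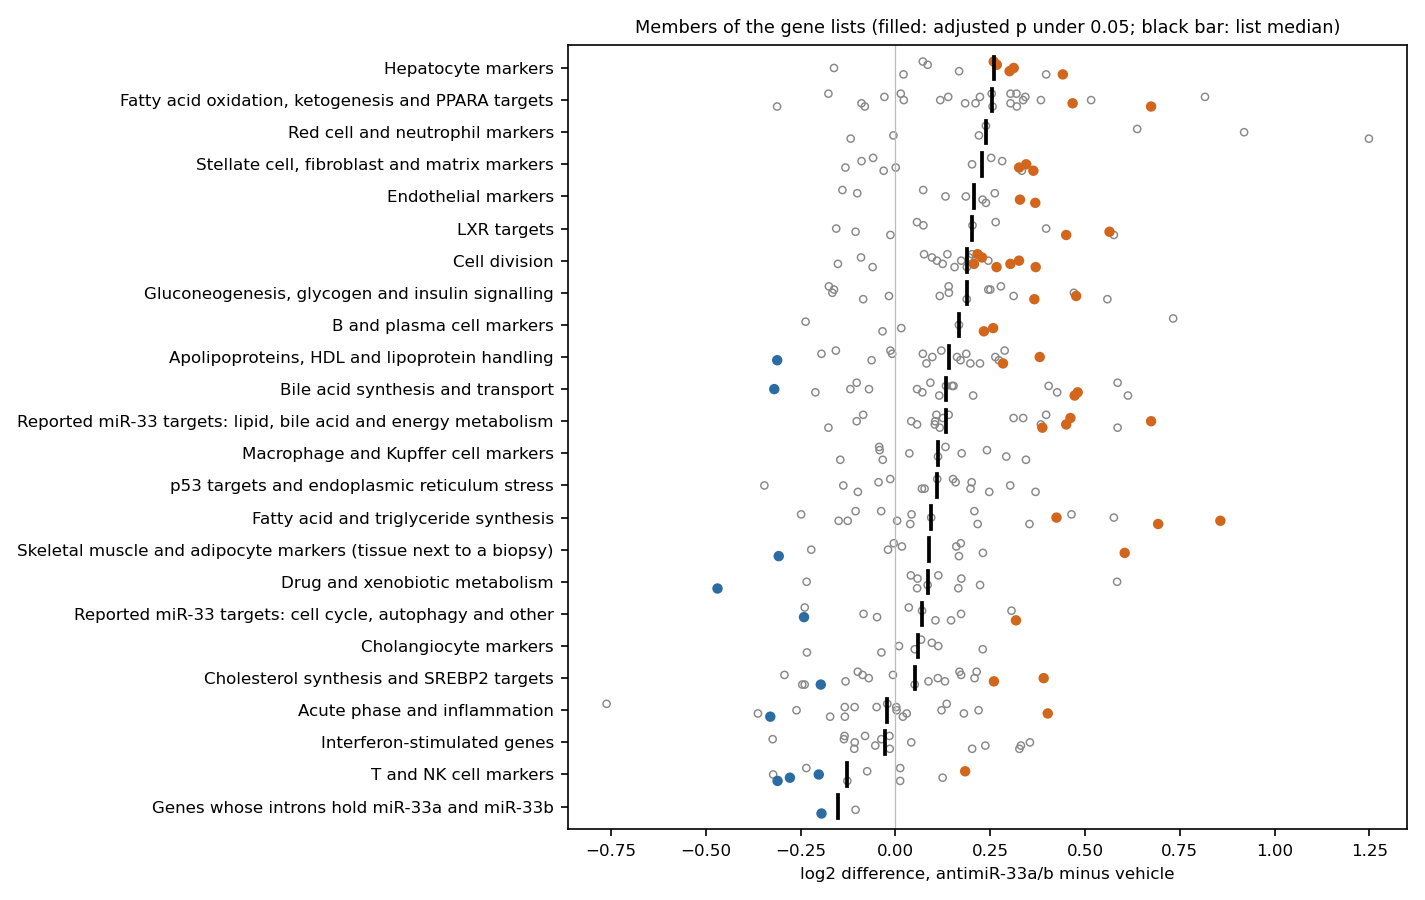
Log2 difference, antimiR-33a/b minus vehicle (x axis), of every measured member of the 24 gene lists (y axis, sorted by median); each point is a gene, filled orange (higher) or blue (lower) where the limma adjusted p was under 0.05, and black bars are list medians. The hepatocyte list has the highest median, 0.26, and the T and NK cell list a median of -0.13.

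The 10 named rises ranged from 0.75 to 0.93. They were SOWAHC (0.93, SE 0.12, limma adjusted p = 0.0014), PPP1R3C, a glycogen-targeting subunit of protein phosphatase 1 (0.84, SE 0.24, adjusted p = 0.0263), the splicing-related gene PNISR (0.78, SE 0.069, adjusted p = 0.0005), the amino acid transport subunit SLC3A1 (0.78) and TXNIP, which binds thioredoxin (0.76). NET1 (0.76), GLO1, the glyoxalase (0.75), ITM2A (0.75), YWHAB (0.75) and REEP3 (0.75) completed them. The 10 named falls ranged from -0.70 to -0.56: the vomeronasal receptor VN1R5 (-0.70, SE 0.085, adjusted p = 0.0012), the delta opioid receptor OPRD1 (-0.69, SE 0.094), the airway secretory gene SCGB1A1 (-0.62, SE 0.068), NOL4L (-0.62), GPC1 (-0.60), PTGIS, the prostacyclin synthase (-0.60), TOR4A (-0.59), EAF1 (-0.58), NTN1 (-0.58) and PRR35 (-0.56). Vomeronasal receptors are among the families taken below as silent in liver, where 90 of 98 called genes were lower. With signal over background unknown, a fall of VN1R5 or another named gene need not be a fall of its transcript. PPP1R3C missed the threshold without treated animal 1 or 4 (adjusted p up to 0.0643) and NOL4L without treated animal 1, 3 or 5 (up to 0.0603). In the fit with the family contrast as a covariate, PPP1R3C (1.18), SLC3A1 (0.66), TXNIP (0.45), GLO1 (0.56), NOL4L (-0.28), PTGIS (-0.35), TOR4A (-0.33) and NTN1 (-0.37) missed it and the other 12 passed. Chosen after their values were seen, NUCB2 had the largest rise of all called genes (1.04) and STAT3, a cytokine-response transcription factor, the largest fall (-0.75).

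**Figure D3:**
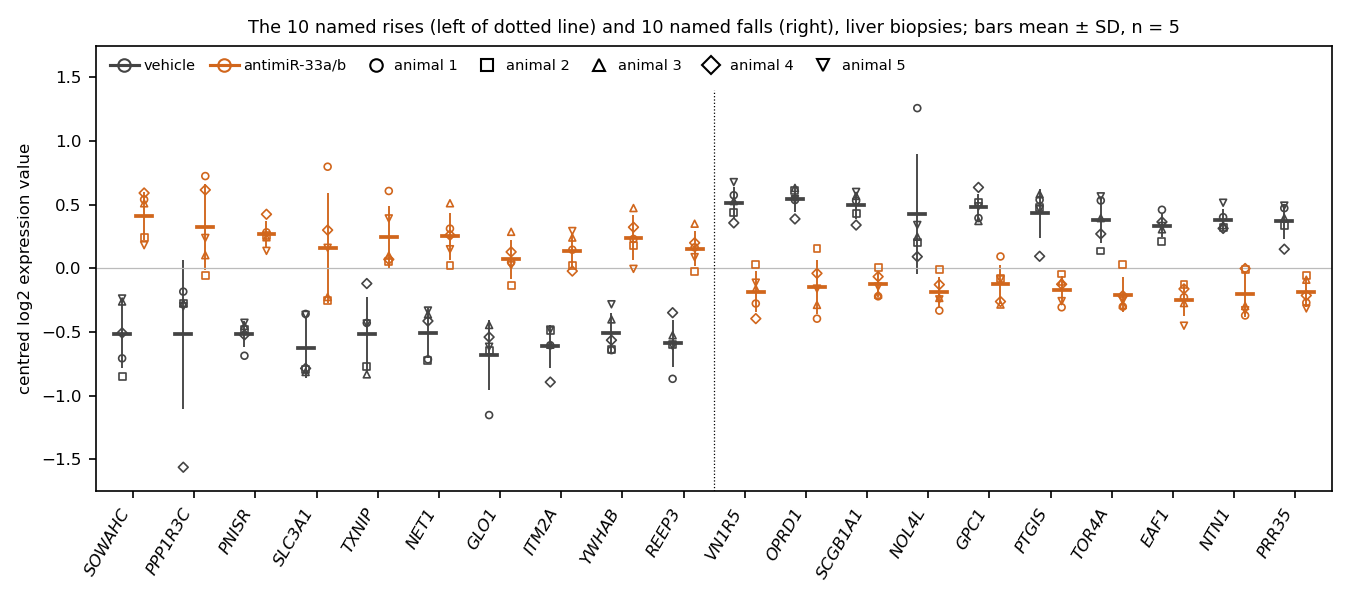
Centred log2 expression values (y axis) of the 10 named rises and, right of the dotted line, the 10 named falls (x axis) in each of 5 vehicle (grey) and 5 antimiR-33a/b (orange) animals; horizontal bars are means, vertical lines SD and marker shapes animals. All treated values lie on one side of all vehicle values, as the choice of these genes required, and vehicle animal 4 has a PPP1R3C value of -1.56.

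Differences were small for most called genes: the median absolute difference was 0.30, 168 rises and 29 falls exceeded 0.50, and 1 gene exceeded 1. In 2207 genes (13.3%) the groups did not overlap, where chance gives 0.794%. The share of calls that were higher was 66.8% as deposited, 54.3% after quantile normalization (1784 higher, 1504 lower) and 58.6% after a shift of the arrays to the same median. The count was 1925 without vehicle animal 1, 2135 without vehicle animal 2 and 2030 without treated animal 3. Permuted gene by gene, 0 genes passed the adjusted threshold: the smallest exact permutation p that 10 animals can give, 0.0079, was reached by 2207 genes and came to an adjusted p of 0.0596.

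Some features of genes that liver does not normally express were called. Of 513 genes in olfactory, taste, vomeronasal, keratin-associated, cornified envelope and beta-defensin families, 90 fell and 8 rose, or 19.1% called, against 20.5% of all genes. The share called ran from 13.6% of 361 olfactory receptors to 59.3% of 27 cornified envelope genes. The median of 532 genes of housekeeping families was -0.13 ± 0.048 (SD, n = 5) in vehicle and 0.050 ± 0.055 (SD, n = 5) in treated animals (exact permutation p = 0.0079, the smallest possible). The median of the silent families was 0.061 ± 0.079 and -0.020 ± 0.079 (exact permutation p = 0.135). The contrast between both medians was higher by 0.26 in treated animals (exact permutation p = 0.0159). Over the animals the contrast correlated with the group at 0.78, and its families were chosen after the values had been examined. A call that ends with it as a covariate therefore does not by itself show that the difference was due to the contrast. With that contrast as a covariate 1076 genes passed, 506 of the 3399 calls remained with the same sign, and 16 of the 66 called genes that the naming rule gave remained called, among them ALB, TIMP1, SOWAHC, PNISR and GPC1. Of the called differences 67.1% was left, with a median ratio of standard errors of 1.35. Of the 50 named genes no longer called, 13 had differences at least as large as before, among them ABCA1, PRKAA1, TF, AHSG, PIK3R1 and MZB1. Another 22 shrank by less than 50%, 13 by more, among them NKG7, SC5D and CROT, and 2, ACADM and ABCG5, turned sign. Vehicle animal 4 stood apart from its group: its mean correlation with the other vehicle animals was 0.0955, against 0.354 to 0.439 for the others' means within the group, and 4117 genes passed without it. Treated animals had equally low means within their own group, from 0.031 (treated animal 2) to 0.115 (treated animal 3). A low mean was therefore unusual among vehicle animals only.

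**Figure D4:**
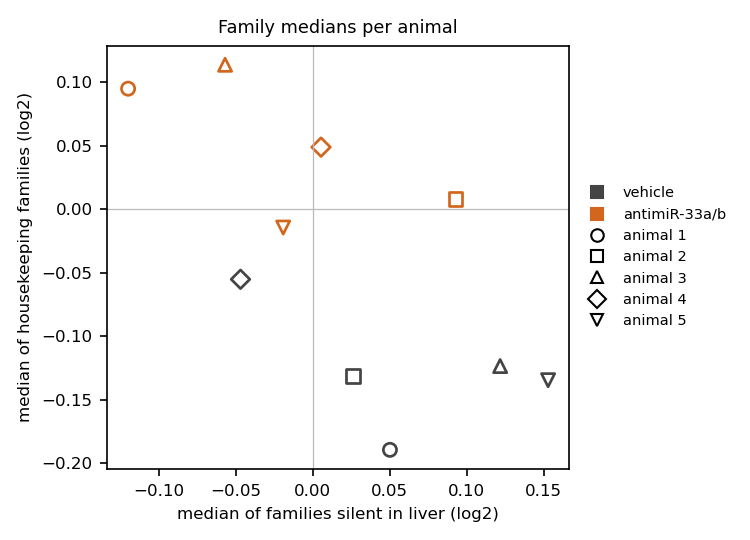
Median centred log2 value of 513 genes of families silent in liver (x axis) and of 532 genes of housekeeping families (y axis), 1 point per animal, vehicle in grey and antimiR-33a/b in orange, marker shapes giving the animal. All 5 treated animals lie above all 5 vehicle animals on the y axis, and vehicle animal 4 has the highest housekeeping median of the vehicle animals, -0.055.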

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

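Chosen only after the results were seen were the tests on quantile normalized values, on the family contrast as a covariate and on the share of hepatocytes. Single animals stood far from the rest of their group in 20 of 196 tests of named genes and array measures, where chance gives about 1 in 20, or 9.8. In vehicle animal 4, HADHB was 0.62 (others -0.34 to -0.064), PPP1R3C was -1.56 (others -0.30 to -0.18), PTGIS was 0.095 (others 0.46 to 0.58) and SOCS3 was 0.49 (others 0.20 to 0.26). Its score on the first principal component of the 10 arrays was 1.17, against -18.1 to -12.8 for the other vehicle animals. In vehicle animal 1, ABCG1 was -0.91, CYP7A1 was 0.39, GLO1 was -1.15, NOL4L was 1.26 and TF was -0.40. In treated animal 1, SLC2A2 was 0.70, ALB was -0.10 and AMBP was -0.023. In treated animal 2, TOR4A was 0.028. In treated animal 3, SIRT6 was -0.28, PPARGC1A was 1.37, APOC3 was -0.0053 and LYZ was 0.46. In treated animal 5, G6PC1 was 0.31 and TIMP1 was -0.082. Outside the named genes, 5747 of the 26845 features without a gene symbol (21.4%) passed the adjusted threshold, 2897 higher and 2850 lower in treated animals.

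The first pattern is the count of 3399 called genes. Among 100 splits of the 10 animals, only the real one gave as many genes. The highest of the others gave 1874, by exchanging vehicle animal 4 and treated animal 2. This argues against chance but cannot exclude it, since 100 splits allow no share under 1 in 100. An exact permutation test per gene gave 0 genes past the adjusted threshold (lowest adjusted p = 0.0596). Array-wide scaling as the whole cause is argued against, since 81.4% of called genes were called with the same sign after quantile normalization. The share of higher calls differed by -0.32 percentage points between bright and dim features, which argues against a difference between these 2 classes. In families silent in liver 8.16% of calls were higher, which this split did not show. A finer trend with brightness was therefore not tested and stays open. Signal other than the named transcript stays open, as 19.1% of genes in families silent in liver were called. That share was uneven, from 13.6% of olfactory receptors to 59.3% of cornified envelope genes. Outside this set it was 7.41% for neurotransmitter receptors and 25.6% for forkhead factors. Also open is a contrast between expressed and silent genes that varies among animals, such as RNA quality or labelling could bring. With that contrast as a covariate 67.1% of the called differences was left (median absolute difference 0.30 before and 0.20 after, median SE 0.073 before and 0.096 after). Of the 2893 calls that ended, 456 differences were at least as large as before and 1191 shrank by less than 50%. Another 1170 shrank by more than 50% and 76 turned. Since the contrast correlated with the group at 0.78, treatment and this contrast cannot be told apart for any of the 2893, whatever the shrinkage.

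The second pattern is vehicle animal 4. On the genes called without it, its position between the vehicle mean (0) and the treated mean (1) was 0.469, against -0.14 to 0.16 for the other vehicle animals (SD 0.15) and 0.62 to 1.13 for treated animals. A wrong label was to give a position over 0.75, and a right one a position under 0.5; it met the second by less than the spread of the other vehicle animals. A wrong label and an animal that differs for other reasons therefore cannot be told apart, and treated animal 2, at 0.62, was the lowest of its group.

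The third pattern is the rise of hepatocyte markers. An equal shift of all genes is argued against, because relative to the median of all genes the list still lay higher by 0.22. That median includes silent families, so it cannot test a rise shared by expressed genes. Median differences of housekeeping families ran from 0.12 (RAB GTPases) to 0.27 (proteasome subunits), against 0.26 for the list. With the family contrast as a covariate the list's median was 0.11. ALB, TF, AMBP and AHSG then had differences at least as large as before. A rise shared by expressed genes therefore stays open. A higher share of hepatocytes in treated biopsies would lower the markers of other cell types, and the median of 76 such markers differed by 0.030 (SE 0.026, exact permutation p = 0.254), so this stays open. An earlier form of this test, a bootstrap over the genes instead of the animals, gave a median of 0.10 (95% interval 0.013 to 0.17), which speaks against it but counts correlated genes as independent. A response of hepatocytes to the treatment stays open as well and was not tested.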

How the results depend on the processing

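Chosen only after the data were examined were the tests with the largest-spread feature, with bright features (values of 8 or more before centring) with the family contrast as a covariate and with both that covariate and an estimated correlation in camera; the cause of each change below was not tested unless given. The exact permutation p of ABCA1 passed in all settings run, with differences of 0.38 to 0.52 without single animals, but its limma call ended with the covariate (0.45, adjusted p = 0.123; 0.0089 to 0.0122 with array weights or trend). Genes changed numbered 1925 to 4117 without single animals (1289 to 2514 higher, 636 to 1603 lower), 1710 with bright features (1135 and 575; fewer genes tested), 1076 with the covariate (867 and 209), and 0 (0 and 0) by permutation per gene (lowest adjusted p = 0.0596). The other settings gave 3288 to 4355. Lists past the camera threshold numbered 0 to 3 without single animals and 7 with the covariate (0 with an estimated correlation as well). The covariate turned the sign, to values past no threshold, of NPC1 (-0.00050), ABCB11 (-0.19), HADHB (-0.25), PPARGC1A (-0.11), SLC25A25 (-0.48), G6PC1 (-0.21), ACADM (-0.042), EHHADH (-0.16), HADH (-0.13), ABCG5 (-0.21), ABCG8 (-0.17), PYGL (-0.15), UGT1A1 (-0.0022), NR1I3 (-0.0029), IFI44 (-0.040), IFIT2 (-0.14), IRF7 (0.0012), TNF (0.051), SOX9 (0.035), ANXA4 (-0.054), C1QC (-0.25), VSIG4 (-0.38) and MS4A1 (0.21). It also turned the list medians of cholesterol synthesis (-0.13), fatty acid synthesis (-0.0029), fatty acid oxidation (-0.16), bile acid (-0.19), lipoprotein (-0.037), LXR (-0.21), glucose (-0.11), xenobiotic (-0.0022), endothelial (-0.016) and macrophage genes (-0.37); the cholesterol synthesis, fatty acid oxidation, bile acid, lipoprotein, LXR and macrophage lists then passed in camera at the preset correlation, as did interferon genes (-0.047). Array weights turned IRS2 (0.051), bright features the cholesterol synthesis (-0.086) and acute phase (0.030) medians, and the largest-spread feature the macrophage median (-0.0043). Without single animals, differences ranged from -0.0065 to 0.14 for ABCB11, -0.36 to 0.082 for CPT1A, -0.23 to 0.068 for IRS2, -0.017 to 0.37 for SLC25A25 and -0.074 to 0.13 for the cholesterol synthesis median. Over all settings, calls of named genes held in 858 of 1071 comparisons, ended in 211 and turned in 2; of 994 comparisons of other named genes 60 passed and 27 turned. The seed-site comparison, its 2 site rules and the log2 offset were not run. No paired analysis was possible because the labels give no numbers shared between groups. Unknown signal over background limits statements on dim genes.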

Other observations

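The tests in this part were chosen after the data were examined, on gene families defined by symbol. The 9 families of general cell functions had positive median differences. Among cytosolic ribosomal proteins 41 of 76 genes rose and 1 fell (median difference 0.24), among splicing factors 32 of 66 rose and 0 fell (0.22), and among translation initiation factors 21 of 51 rose and 1 fell (0.22). Proteasome subunits rose in 19 of 40 cases and fell in 0 (0.27), mitochondrial ribosomal proteins rose in 28 of 77 and fell in 1 (0.18), and respiratory chain and ATP synthase subunits rose in 28 of 84 and fell in 5 (0.18). Ubiquitin-conjugating enzymes rose in 11 of 27 and fell in 0 (0.14), RAB GTPases rose in 14 of 71 and fell in 2 (0.12), and vesicle coat proteins rose in 7 of 40 and fell in 0 (0.15; 17.5% called, under the share of all genes). After quantile normalization the medians of the first 6 were 0.20, 0.16, 0.17, 0.18, 0.13 and 0.13, so no direction turned among them. The vesicle coat family then missed the camera threshold (adjusted p = 0.113). With a preset correlation camera gave adjusted p of 7.2e-10 for splicing factors, 2.1e-09 for cytosolic ribosomal proteins and 0.0018 for the respiratory chain, and none of the 19 families passed with an estimated correlation (lowest adjusted p = 0.362).

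Cornified envelope genes fell in 16 of 27 cases and rose in 0 (median difference -0.22), keratin-associated proteins fell in 19 of 67 and rose in 0 (-0.12), and olfactory receptors fell in 45 of 361 and rose in 4 (-0.075). Taste and vomeronasal receptors fell in 5 of 30 and rose in 1 (-0.068), and beta-defensins fell in 5 of 28 and rose in 3 (0.0075). The medians kept their sign under quantile normalization and under a shift of arrays to the same median. Neurotransmitter receptors, with 2 of 81 higher and 4 lower, potassium channels, with 1 of 86 higher and 8 lower, and homeobox factors, with 3 of 83 higher and 7 lower, had shares called of 7.41%, 10.5% and 12.0%, against 20.5% of all genes, which were not compared by a test. The shares were 17.1% for zinc finger factors (34 higher and 39 lower of 426) and 25.6% for forkhead factors (7 higher and 4 lower of 43). ADH7 had the most negative mean difference of any gene (-1.22, adjusted p = 0.125), with an SD of 1.53 among vehicle animals, and was named after its value was seen.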
